A study of Caenorhabditis elegans with 2 samples.

How the data were processed

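The series holds ChIP-seq of SNPC-4 from whole *Caenorhabditis elegans* at the L2 larval stage, with 2 biological replicates in 1 group, per the labels. SNPC-4 is a subunit of the small nuclear RNA activating protein complex, which binds upstream of small nuclear RNA genes. The worms carried an eGFP-tagged *snpc-4* transgene in an *unc-119* mutant background, and library fragments were 150 to 350 bp long per the labels. No second condition was labelled, so the comparisons were between gene classes, between peaks that passed the reproducibility threshold and other candidate peaks, and between the replicates.

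Only peak lists were used, on the ce10 and ce11 builds. Per the deposited description files, peaks were called by the authors for each replicate and for the pooled reads against a control alignment. These relaxed lists were given as input to the irreproducible discovery rate procedure (IDR), which compares the ranks of peaks between lists. Not every peak of the resulting list was found in both replicates. Of 1864 peaks on ce11, 1744 overlapped a replicate 1 peak and 1856 a replicate 2 peak. The aligner, the peak caller and their versions were not given in the sources used here. The deposited signal value of a peak is the authors' peak-caller strength. Whether it was scaled to depth was not stated, so strengths were compared only between peaks of 1 list. The exception was the correlation between replicates, which paired signals from both replicate lists. The deposited −log10 q value was read only to describe the lists. No read count was at hand, so sequencing depth was unknown and the intervals given cover counting of genes and peaks only.

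On ce11 the replicate 1 list held 21391 peaks, while the replicate 2 and pooled lists each held exactly 30000. The IDR list held 1864 peaks on ce11 and 1907 on ce10. All 1864 IDR peaks were in the pooled list, and they were its 1864 strongest, with a lowest signal of 28.0. The IDR list was thus a threshold on pooled signal, and comparing it with other candidates compared strong with weaker regions. The IDR list and the pooled list each held 25 mitochondrial peaks, as did replicate 2, and replicate 1 held 0.

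Gene positions came from Ensembl release 115 on WBcel235, the assembly of ce11, and the ce10 lists were used only where no gene position was needed. The tests, gene lists and named-gene rule were set before the data were examined. A peak was assigned to a noncoding class if its summit lay within 250 bp of a gene body, and to a protein-coding promoter if it lay within 500 bp of an annotated transcript 5' end. The classes were snRNA, SL RNA, tRNA, 5S rRNA, snoRNA, miRNA and piRNA. Enrichment was the odds ratio of IDR peaks against the other candidate peaks of the pooled list, with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over classes, chromosomes or lists. It was the plain sample ratio, 0 where no IDR peak or list member was counted, a form chosen after the results were seen that left the p values unchanged. Occupancy was the share of genes with an IDR summit, with an exact (Clopper-Pearson) 95% interval. Peak strength was compared with 100000 permutations of the median log2 signal, and replicate overlap with 1000 circular shifts. piRNA clusters were 100 kb bins of chromosome IV with at least 50 annotated piRNA genes. Sequences of 8 bases in the 50 bp each side of the summit were tested with a two-sided hypergeometric test.

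Named genes were the nearest genes of the 10 strongest IDR peaks, with the nearest gene of the listed classes where another gene was nearer, the 3 genes of each class with the strongest peak, and the 10 protein-coding genes with the strongest promoter peak lacking a listed noncoding gene. From each fixed list all bound members were named if 5 or fewer, otherwise the 4 strongest. *snpc-4* and *unc-119* were always included. Families of snRNA genes were assigned from conserved sequence or gene name, a step chosen after the data were seen. The positions of summits in exons and introns and the split of tRNA genes by genome were also added then.

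The alternatives were a stricter list of 932 peaks, circular shifts as background, each replicate alone, other windows, fixed cluster bounds and the ce10 lists. A repeat without the mitochondrial genome was added after the data were seen. Simulated lists held 30000 peaks placed at random on the nuclear chromosomes, with a planted snRNA signal. On them the class test called snRNA in 20 of 20 simulations and another class in 2 of 120 tests. Random placement leaves out differences between strong and weaker regions, so false calls from those were not covered. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.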

Results

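SNPC-4 binding was mapped by ChIP-seq of an eGFP-tagged protein in 2 biological replicates of L2 larvae. The list of peaks that passed IDR held 1864 peaks on ce11, with signal values from 28.0 to 3852 and a median of 43.7. Summits lay between protein-coding genes for 1339 peaks (71.8%, 95% interval 69.7 to 73.9), in introns for 417, in coding exons for 40 and in untranslated exons for 68. Among the 28136 other candidate peaks, 47.0% lay between genes (odds ratio 2.88, Fisher's exact test, adjusted p = 5.47e-98). The 40 summits in coding exons include mitochondrial ones, such as those at *MTCE.26* and *MTCE.12*. These positions were not counted again without the mitochondrial genome.

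The first comparison asked which noncoding gene classes carried SNPC-4. Peaks were concentrated at small nuclear RNA, trans-splicing leader (SL) RNA and small nucleolar RNA genes. Summits within 250 bp of an snRNA gene made up 37 of 1864 IDR peaks against 22 of 28136 other candidates (odds ratio 25.9, 95% interval 15.2 to 44.0, Fisher's exact test, adjusted p = 1.31e-29). SL RNA genes, which encode the leader spliced onto many worm mRNAs, accounted for 14 IDR peaks against 4 other candidates (odds ratio 53.2, Fisher's exact test, adjusted p = 4.13e-14). For snoRNA genes the counts were 70 and 97 (odds ratio 11.3, Fisher's exact test, adjusted p = 2.45e-39). tRNA genes had 83 IDR peaks against 274 other candidates (odds ratio 4.74, Fisher's exact test, adjusted p = 9.89e-26), and 69 against 274 on the nuclear chromosomes (odds ratio 3.96). miRNA genes had a smaller excess, with 10 against 55 peaks (odds ratio 2.75, Fisher's exact test, adjusted p = 0.00763). piRNA genes were depleted among IDR peaks relative to the weaker candidates, with 35 against 1643 peaks (odds ratio 0.309, Fisher's exact test, adjusted p = 5.67e-16). The size of this depletion depended on the setting, with ratios of 0.580 against circular shifts (permutation test, adjusted p = 0.00233, the smallest adjusted value these shifts gave for a class), 0.492 with replicate 1 alone, 0.301 with replicate 2 alone, 0.126 at 100 bp and 0.369 at 500 bp, each past the threshold. At 5S rRNA genes there were 0 IDR peaks and 1 other candidate, too few to compare.

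By gene, 38 of 99 snRNA genes (38.4%, 95% exact interval 28.8 to 48.7) and 14 of 30 SL RNA genes (46.7%, 28.3 to 65.7) had an IDR summit. The 38 snRNA genes include *mir-1831*, which is 22 bp long and was counted by its annotated class despite its name. The share was 71 of 346 for snoRNA genes (20.5%, 16.4 to 25.2) and 76 of 612 for nuclear tRNA genes (12.4%, 9.91 to 15.3). Of 22 mitochondrial tRNA genes 18 lay within 250 bp of a summit, a count that chance gives, since 76.1% of the mitochondrial genome lay that near and circular shifts of its summits gave a mean of 17.3 genes (one-sided permutation p = 0.501, a test added after the data were seen). Only 51 of 15363 piRNA genes (0.332%, 0.247 to 0.436) had one. For piRNA genes the count was 31 in the stricter list, 15 at 100 bp and 116 at 500 bp. For miRNA genes it was 10, with 6 at 100 bp and 19 at 500 bp. The stricter list lowered the tRNA count, both genomes together, from 94 to 51.

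**Figure D1:**
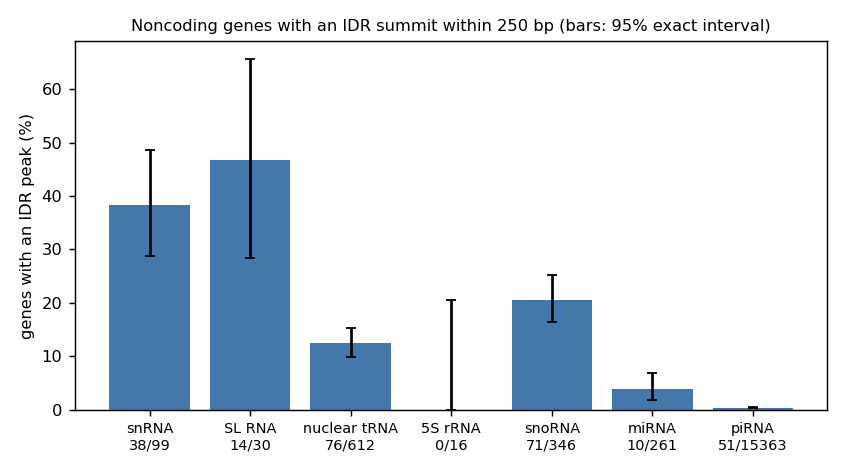
Share of genes of each noncoding class with an IDR summit within 250 bp (y axis, percent), with 95% exact intervals as error bars and gene counts under each class. SL RNA (46.7%) and snRNA genes (38.4%) had the highest shares and piRNA genes (0.332%) the lowest share above 0.

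Within these classes the families differed in their share of bound copies. Peaks lay at 9 of 12 genes for U1, the RNA that recognises the 5' splice site, and at 9 of 12 for U5. Counts were 5 of 20 for U2, 2 of 5 for U4 and 6 of 22 for U6. SmY RNA genes, a nematode family linked to trans-splicing, had peaks at 6 of 12, with 5 distinct peaks. Of these 6, *smy-2* and *smy-3* are annotated as snoRNA and were counted in that class above, and *smy-1* was counted from a summit 307 bp past its 5' end. For the SL RNAs, 14 of 18 SL2 genes were bound and 0 of 12 SL1 genes. All 12 SL1 genes had an identical copy, as had 17 of the U6 genes and 9 of the U2 genes, so their low counts may reflect reads that could not be placed. Mappability could not be checked without reads, and the region upstream of the genes, where summits lay, was not compared. The SL1 and 5S rRNA genes on V, 27 in all, lie in a span of 313 kb. That span held 52 pooled candidates, but only 1 of the 27 genes had one within 250 bp. The absence of IDR peaks at 5S rRNA genes is thus subject to the same limit. Identical copies did not rule out strong peaks, since *R07E5.16* (U6), *T11F9.15* (U4) and *F38E11.11* (U5), named below, each have them. These shares were not tested against each other.

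The strongest peak of the list (signal 3852, II, 15025769 to 15026157) had its summit 88 bp from the snoRNA gene *Y53F4B.47*. Next came *sls-2.4* (3588), the U6 gene *R07E5.16* (3418, gene at III, 10989679 to 10989780) in an intron of *dhc-4*, a peak 56 bp from the unclassified noncoding RNA gene *F08G2.13* (2859), and *sls-2.8* (2740). The other peaks of the 10 strongest were at the snoRNA gene *ZK994.7* in an intron of *pxn-1* (2703), *sls-2.2* (2457), the U4 gene *T11F9.15* (2194), *sls-2.1* (1967) and the snoRNA gene *Y37E3.20* in an intron of *pcyt-2.1* (1954). The annotation gives the name *R07E5.16* to 14 genes, 5 of them with a peak, and the name *T11F9.15* to 2 genes. At 5 of the 10 peaks the nearest gene was an unclassified noncoding RNA gene, *F08G2.13* as given above and 4 beside a gene of the listed classes. These were *R12E2.18* at *sls-2.4* (54 bp), *Y75B8A.49* at *sls-2.8* (48 bp), *C17C3.23* at *sls-2.2* (29 bp) and *C52E4.14* at *T11F9.15*, which spans the summit. The unclassified noncoding RNA gene *Y37E3.29* likewise spans the summit at *Y37E3.20*. The 5 peaks with such a gene beside one of the listed classes cannot be given to 1 gene by distance. Of the 10 strongest peaks 9 were at snRNA, SL RNA or snoRNA genes, as were 51 of the 100 strongest and 28 of the 932 weakest. The third snRNA gene by strength was the U5 gene *F38E11.11* (1948, gene at IV, 9444642 to 9444763), a name given to 2 genes. Among other RNA polymerase III transcripts, chosen after their values were seen, the RNase P RNA gene *rpr-1* (signal 1728, rank 12) and the RNase MRP RNA gene *mrpr-1* (1285, rank 22) had strong peaks, and the Y RNA gene *yrn-1* a weaker one (55.4, rank 604).

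At the tRNA genes the strongest nuclear peak was at *K11H12.t1* (signal 893), and the other leading ones were nearest to mitochondrial tRNA genes (1515 and 829). The summit of the stronger lay 247 bp from the tRNA gene, inside the coding gene *MTCE.21*. The miRNA genes with the strongest peaks were *mir-2214* (1021), *cel-mir-8196a* (390) and *cel-mir-5549* (93.8). At piRNA genes they were *21ur-7591* (620), *21ur-916* (106) and *21ur-12279* (98.8). The first 2 summits lay 234 and 194 bp downstream of the piRNA 5' end. The third lay 130 bp upstream and 22 bp from the 5' end of the coding gene *atp-1*, so these signals need not belong to the piRNA genes.

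The next comparison was of peak strength with the 918 promoter peaks that had no listed noncoding gene, whose median signal was 44.2. SL RNA peaks had a median of 524 (quartiles 265 and 1652, n = 14), 3.56 higher on the log2 scale (permutation test, adjusted p = 3.00e-05). snRNA peaks had a median of 100.4 (log2 difference 1.18, adjusted p = 3.00e-05, n = 37), and snoRNA peaks 60.01 (log2 difference 0.44, adjusted p = 1.00e-04, n = 70). The snoRNA difference was 1.01 with replicate 1 alone and 0.34 with replicate 2 alone. For SL RNA and snRNA the unadjusted p was 1e-05, the smallest the permutations can give. tRNA peaks had a median of 44.0 (permutation test, adjusted p = 0.979), and 41.9 on the nuclear chromosomes (permutation p = 0.366). No difference passed the test for piRNA peaks (45.9, permutation test, adjusted p = 0.780). For miRNA peaks the result depended on the window, with no difference past the threshold at 250 bp (57.5, log2 difference 0.38, permutation test, adjusted p = 0.150) and a log2 difference of 0.97 at 100 bp (permutation test, adjusted p = 0.00915).

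**Figure D2:**
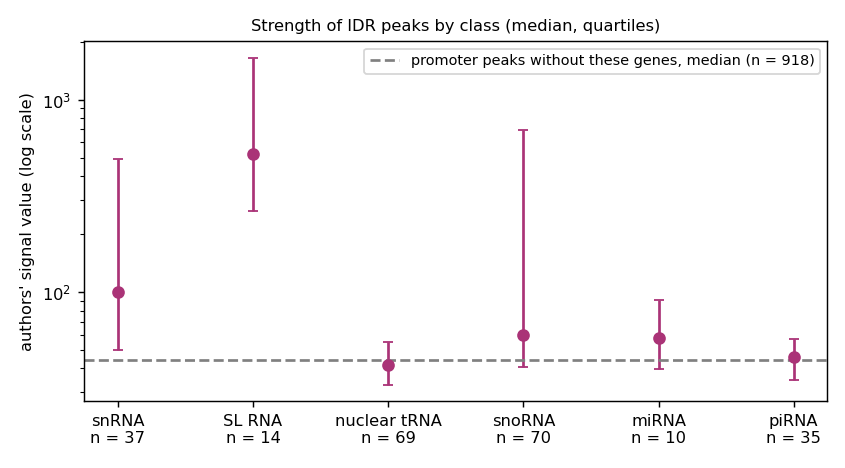
Median and quartiles of the authors' signal value (y axis, log scale) of IDR peaks by noncoding class, with the median of promoter peaks as a dashed line at 44.2. SL RNA (524) and snRNA peaks (100.4) lay above the line and nuclear tRNA peaks (41.9) near it.

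Summits lay upstream of the RNA start at snRNA, SL RNA and snoRNA genes. The median distance was 53.5 bp upstream of the 5' end for 38 snRNA genes (quartiles 47.3 and 59), 46 bp for 14 SL RNA genes (37.3 and 56) and 53 bp for 71 snoRNA genes (34 and 66). The summit was upstream at 35, 14 and 65 of these genes. At 76 nuclear tRNA genes the median was 20 bp upstream, and 49 summits were upstream of the 5' end (64.5%, 95% exact interval 52.7 to 75.1).

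**Figure D3:**
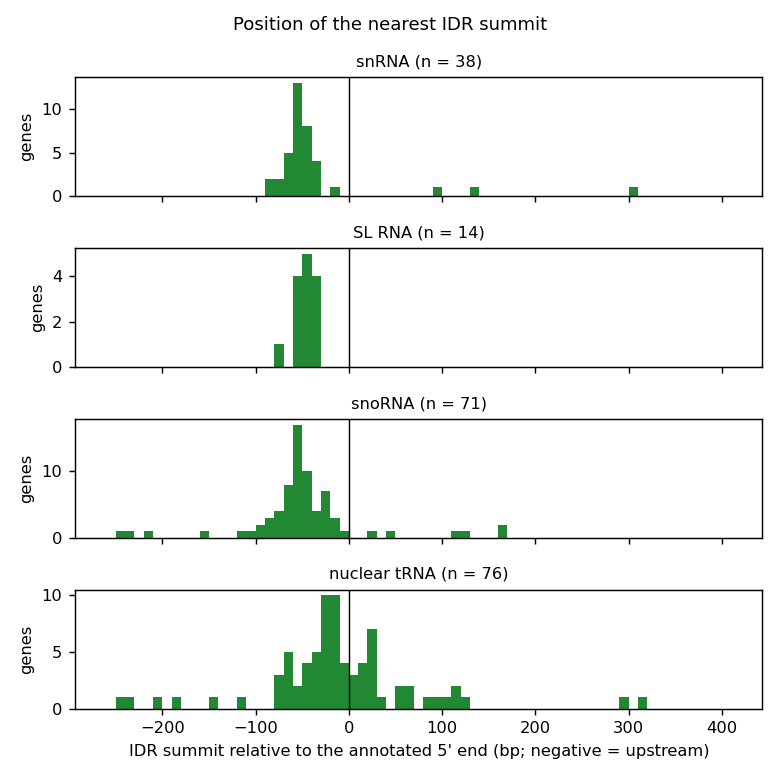
Histograms of the distance from the annotated 5' end to the nearest IDR summit (x axis, bp, negative upstream) for genes with a summit within 250 bp (y axis, genes). snRNA, SL RNA and snoRNA summits centre on 53.5, 46 and 53 bp upstream, and nuclear tRNA summits on 20 bp upstream with a wider spread.

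piRNA genes lie mostly on chromosome IV, and SNPC-4 is known to act at them in the germline, so IV was compared with the rest of the genome. Of the 15363 annotated piRNA genes 14714 were on IV, and 14124 lay in 3 clusters that together span 5.4 Mb. Chromosome IV held 278 of 1864 IDR peaks (14.9%, 95% exact interval 13.3 to 16.6) against 18.7% of other candidates (odds ratio 0.760, Fisher's exact test, adjusted p = 9.66e-05). Chromosome V was also depleted (odds ratio 0.776) and I and II were enriched (1.19 and 1.23), each past the threshold after adjustment. The clusters held 80 IDR summits (4.29%) against 1995 other candidates (7.09%, odds ratio 0.588, Fisher's exact test, p = 1.13e-06). Against circular shifts of the IDR peaks the cluster count was not different (80 observed, mean 86.0, permutation p = 0.539). With replicate 1 alone the odds ratio was 0.865 (Fisher's exact test, p = 0.240). The cluster at 4800001 to 6300000 held 21 IDR summits and that at 13600001 to 17300000 held 56.

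**Figure D4:**
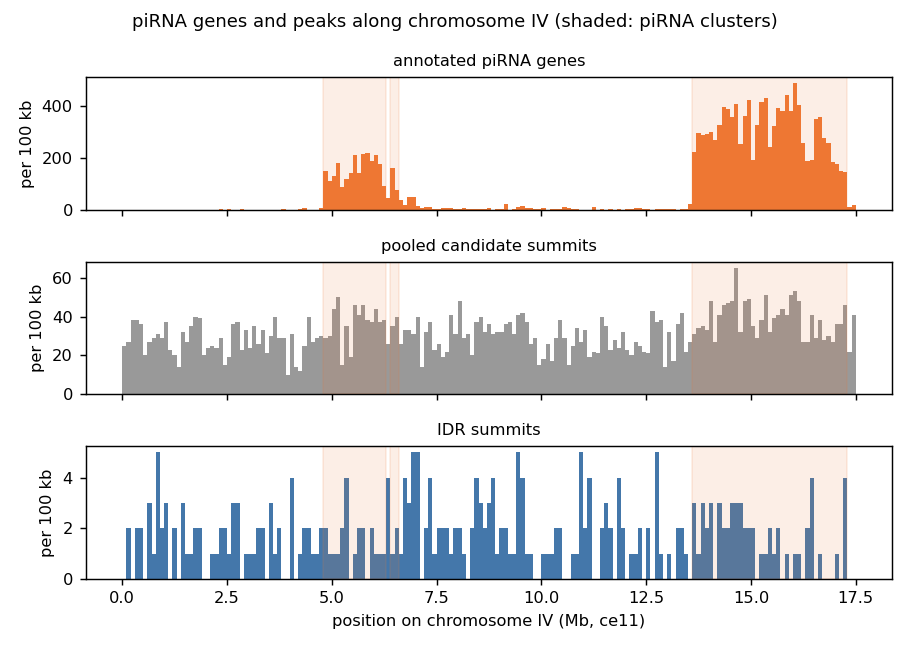
Annotated piRNA genes, pooled candidate summits and IDR summits per 100 kb along chromosome IV (x axis, Mb, ce11), with piRNA clusters shaded. The clusters held 80 of the 278 IDR summits on this chromosome.

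At protein-coding genes, 987 IDR peaks (53.0%, 95% exact interval 50.7 to 55.2) lay within 500 bp of a 5' end, against 27.1% of other candidates (odds ratio 3.03, Fisher's exact test, p = 3.37e-114). A promoter summit was found at 1267 of 19985 protein-coding genes (6.34%). Ribosomal protein genes stood apart, with a peak at 59 of 81 (72.8%, 61.8 to 82.1) against 6.07% of other genes (odds ratio 41.5, Fisher's exact test, adjusted p = 5.02e-52). The odds ratio was 7.74 at 250 bp around the 5' end (Fisher's exact test, adjusted p = 7.01e-10) and 31.4 to 43.4 in the other settings. Their strongest peaks were at *rpl-15* (signal 389), *rpl-3* (271), *rpl-20* (265) and *rpl-22* (214). The *rpl-20* summit lay nearer the 5' end of *Y17G9B.5* (-169 bp against -293 bp, negative upstream). The *rpl-22* summit lay nearer that of *ify-1* (-192 bp against -245 bp). No other coding gene had a 5' end within 500 bp of the *rpl-15* or *rpl-3* summit. Ribosomal protein genes can share a peak, as *rps-10* and *rpl-24.1* did, so 59 counts genes, not separate peaks. Which gene a shared peak belongs to was not tested. The other 8 lists did not pass the test. Histone genes were bound at 4 of 72 (Fisher's exact test, adjusted p = 1), namely *his-37* (180), *his-24* (57.7) and the neighbours *his-67* and *his-68* that share a peak (44.3). With replicate 1 alone histone genes passed (odds ratio 2.71, Fisher's exact test, adjusted p = 0.0312).

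Of the tissue markers, the sample being the whole animal, 1 of 12 germline genes (*mes-2*, signal 60.1), 1 of 11 body-wall muscle genes (*act-4*, 32.9) and 1 of 12 neuron genes (*unc-31*, 81.0, with a listed noncoding gene beside the summit) had a peak. No peak was found at the 12 intestine, 11 hypodermis, 12 piRNA pathway and 11 SNAPc and RNA polymerase III genes, each list with an adjusted p of 1 by Fisher's exact test, like the 3 marker lists above. With so few members the upper limits were high, at 26.5% for a list of 12 and 28.5% for a list of 11.

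The strongest promoter peaks with no listed noncoding gene were at *pcrg-1* (signal 1285), *C17G10.10* (1054), *W01D2.3* (1009), the mitochondrial *MTCE.26* (431), *npr-23* (426), *rpl-15* (389), *gpa-1* (339), the mitochondrial *MTCE.12* (295), *rpl-3* (271) and *cyp-13A2* (266). Unclassified noncoding RNA genes lay within 250 bp of the summit for *pcrg-1*, *C17G10.10*, *W01D2.3* and *gpa-1*. The one at *pcrg-1* was *mrpr-1*.

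The piRNA upstream motif CTGTTTCA was less frequent at IDR peaks, within 100 bp of 12 summits (0.644%) against 2.66% of other candidates (odds ratio 0.237, Fisher's exact test, p = 6.36e-10). The ratio was 0.0824 within 50 bp and 0.339 against circular shifts. Of 32896 sequences of 8 bases, 3306 were enriched and 1709 depleted around IDR summits after adjustment. The leading one, AGACGCAG, was near 193 IDR summits (10.4%) against 1.53% of other candidates (odds ratio 7.42, exact hypergeometric adjusted p = 1.17e-77). CGGAACCC was near 6.38% of IDR summits against 0.558% of other candidates (odds ratio 12.2, exact hypergeometric adjusted p = 4.02e-65), and GCCGACAC near 116 (6.22% against 0.881%, odds ratio 7.46, exact hypergeometric adjusted p = 2.36e-47). Runs of A such as AAAAAAAA were depleted (3.27% against 16.0%). Within 50 bp, TTTGGAAA (odds ratio 0.103) and TTTCTGAA (0.0843) were depleted about as much as CTGTTTCA. The depletion was thus not particular to the piRNA motif, and base composition was not accounted for. IDR summits also lay more often at protein-coding promoters (53.0% against 27.1%), which the test did not match for. An enriched sequence therefore need not be an SNPC-4 motif.

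The replicates shared their strongest peaks and differed more among weak ones. Of the 1864 strongest peaks of replicate 1, 1165 (62.5%) overlapped 1 of the 1864 strongest of replicate 2 by at least 1 bp, against a mean of 1.01% after circular shifts (one-sided permutation p = 0.000999, the smallest these shifts can give). The overlap was 47 of 50 among the 50 strongest and 80 of 100 among the 100 strongest. The 100 strongest of replicate 2 included 18 mitochondrial peaks, which replicate 1 lacked. On the nuclear chromosomes alone, a repeat added after the data were seen, the overlap was 48 of 50, 89 of 100, 331 of 500 and 1170 of 1864. Across the 1737 IDR peaks present in both lists, log2 signals had Pearson r = 0.784 and Spearman rho = 0.503 (permutation p = 1e-05 each, the smallest the permutations can give). These are correlations across peaks, which are not independent replicates. Every snRNA, SL RNA, snoRNA and piRNA gene peak had an overlapping peak in both replicates, against 1744 of 1864 IDR peaks (93.6%) in replicate 1 and 1856 in replicate 2. tRNA peaks had one in replicate 1 at 65 of 83 (78.3%), where no mitochondrial peak was listed, and miRNA peaks at 9 of 10. In replicate 2 all peaks of both classes had one.

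**Figure D5:**
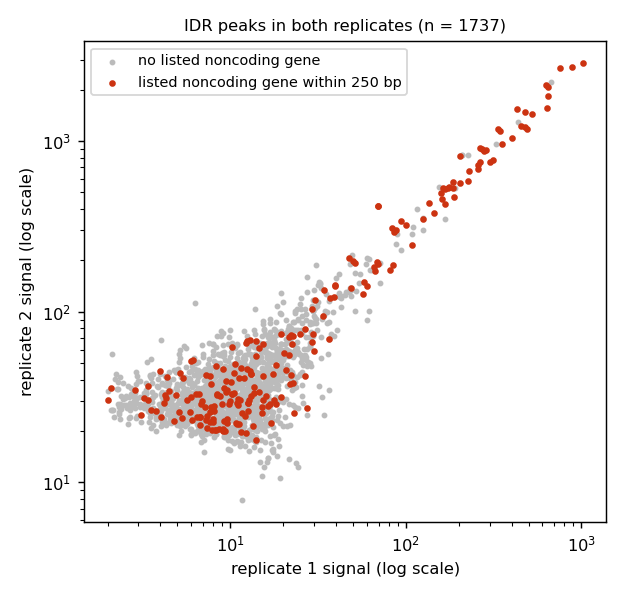
Signal of the strongest overlapping peak in replicate 1 (x axis) and replicate 2 (y axis), both log scale, for the 1737 IDR peaks found in both, with peaks at listed noncoding genes in red. The strongest peaks fall along 1 line, and the weaker ones form a wide cloud (Spearman rho = 0.503).

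The tagged gene *snpc-4* (I, 8962322 to 8966129) had no IDR peak and no pooled candidate within 500 bp. In replicate 1 alone it had 3 candidate summits, the strongest 229 bp before the gene start with signal 23.6. That peak ranked 229 of 21391 in the replicate 1 list, whose median signal was 3.09, while replicate 2 had no candidate there. Its signal belongs to the replicate 1 list and is not on the scale of the pooled signals. The rescue gene *unc-119* (III, 10902641 to 10908935) had no IDR peak and 7 pooled candidates, with a highest signal of 27.2, just under the lowest IDR signal of 28.0. The transgene adds copies of the tagged locus, and the number of copies was not given in the sources used here.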

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

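The test below was set before its result was known, but after the mitochondrial peaks were seen. The mitochondrial genome held 25 IDR peaks, a signal outside the nuclear genes that the comparisons concern. Their median signal was 295, the highest was 1515, and 16 were among the 100 strongest peaks. They covered 6685 of 13794 bp (48.5%). Replicate 2 listed 25 such peaks and replicate 1 listed 0. If the peaks came from coverage of abundant mitochondrial DNA, few should carry the upstream element learned at snRNA and SL RNA genes, and 0 of 25 did (95% exact interval 0 to 13.7%). This shows only that the mitochondrial peaks lacked the element. It was also rare at held-out other candidate peaks (0.832%) and at nuclear tRNA peaks (1 of 68). A count near 0 was therefore likely whatever the origin of the peaks, and the test cannot tell coverage from binding without the element. Removal of mitochondrial peaks from the replicate 1 list before deposit was not tested, and no biological explanation was tested.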

How the results depend on the processing

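There were 187 alternative values for 40 results. Some could hardly change, since 5S rRNA genes and the intestine and hypodermis lists gave 0 in each of theirs. Counting those, 167 of the 187 kept their direction and side of the threshold or moved by less than the limit set. The odds ratios of snRNA, SL RNA, tRNA, snoRNA, miRNA and piRNA genes, of chromosome IV, of promoters and of CTGTTTCA kept both under every alternative run. Their size varied, with ranges of 20.3 to 37.7 for snRNA, 42.5 to 110.8 for SL RNA, 8.10 to 18.1 for snoRNA, 3.96 to 5.42 for tRNA, 2.63 to 3.95 for miRNA and 0.126 to 0.580 for piRNA genes, and 0.0824 to 0.339 for CTGTTTCA. The share in piRNA clusters lost significance against circular shifts (odds ratio 0.928), and gave 0.624 and 0.865 with 1 replicate left out, the latter past the threshold no longer. Pooled candidates were denser in the clusters, which lowers by construction the main odds ratio against other candidates (0.588). The circular shifts do not use those candidates. The cause of the replicate difference was not tested. Circular shifts keep each peak on its chromosome, so they gave no value for the chromosome IV share, and 5S rRNA had no odds ratio at 100 bp for want of candidates. The stricter list, with fewer peaks, gave 51 tRNA genes. The number of gene lists past the threshold was 1 to 2 with 1 replicate left out. miRNA peak strength passed with a 100 bp window (log2 difference 0.97), and piRNA peak strength changed sign in each replicate alone (-0.20 and -0.063), neither value past the threshold; the causes were not tested. Among single lists, histone genes had odds ratios of 1.67 in the stricter list, 2.71 with replicate 1 alone and 0.845 with replicate 2 alone, 1.36 at 250 bp and 1.195 at 1000 bp. Body-wall muscle genes fell to 0 in the stricter list and at 250 bp. Neuron genes had odds ratios of 1.52 with replicate 1 alone and 2.88 with replicate 2 alone, neither past the threshold. With replicate 1 alone the piRNA pathway (1.52) and SNAPc and RNA polymerase III lists (1.67) gained 1 member, *snpc-4*, the tagged gene. Without the mitochondrial genome, chosen after seeing the data, no call changed among the results repeated that way. These were the odds ratios of the classes, chromosome IV, clusters, promoters and CTGTTTCA, and the replicate overlap. Gene lists were not repeated that way, and peak strength only for tRNA. Sequencing depth was unknown and limits what absence of a peak shows.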

Other observations

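The element test on peaks without a listed gene was chosen after 8-base sequences at those same peaks had been seen, so its p value does not stand as an independent test. The other tests here were set before their results were known. An upstream element of 24 bp was learned from the 90 bp before 46 bound snRNA and SL RNA genes. Its consensus was GCGGAACCCGCNAGATGTCGGNAC. Above a threshold passed by 0.832% of 14068 held-out candidates, it was found at 25 of 69 snoRNA peaks (36.2%, 95% exact interval 24.99 to 48.7, odds ratio 67.7), which were not used to learn it. It was found at 2 of 10 miRNA peaks, 4 of 30 piRNA peaks, 16 of 909 nuclear promoter peaks (1.76%) and 1 of 68 nuclear tRNA peaks. Of the 51 snRNA or SL RNA peaks, the classes it was learned from, 33 passed the threshold.

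A group of 706 nuclear IDR peaks (37.9%) had neither a listed noncoding gene nor a promoter. The element was at 93 of them (13.2%, 95% exact interval 10.8 to 15.9; odds ratio 18.1 against held-out candidates, Fisher's exact test, p = 5.72e-67), of which 88 were also in replicate 1. Only 4 of the 93 had an annotated unclassified noncoding RNA gene within 250 bp, *rpr-1* among them. Of the 93, 59 (63.4%) lay inside a coding gene, and several of the strongest were on X. A candidate explanation is genes of the snRNA type outside the listed classes, which needs RNA evidence that was not analysed here. Base composition was not matched between these peaks and the held-out candidates. The strongest of the 93 without an unclassified noncoding RNA gene within 250 bp lay in an untranslated exon of *bed-2* (III, 11463837 to 11464162, signal 511).

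Promoters just outside the 500 bp window may account for part of that group, since 27.5% lay within 1000 bp of a 5' end against 23.4% of held-out candidates (odds ratio 1.24, Fisher's exact test, p = 0.0152). At annotated unclassified noncoding RNA genes, 25 had a summit 30 to 80 bp upstream and 14 the same distance downstream (exact binomial p = 0.108), which does not decide whether these summits mark RNA starts. The window of 30 to 80 bp was chosen after summit distances at other classes had been seen. A p of 0.05 or more had been set in advance as evidence against both tests that use this window, but that bound was wrong, since such a p does not exclude an excess that the intervals allow, so both were left undecided after their results were seen. Most of the group had neither the element nor a 5' end within 1000 bp, and remained without an explanation tested here.

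The low count at piRNA genes was also examined. Pooled candidates were denser in the clusters, with 2075 summits against a mean of 1728 after circular shifts along IV (permutation p = 0.002, the smallest these shifts can give). Denser candidates lower the ratio against other candidates but not the count of piRNA genes with a peak. These candidates were themselves called as ChIP peaks against a control, and whether their excess in the clusters is binding was not tested. A low ratio against them therefore shows few strong peaks, not absence of SNPC-4. Circular shifts of the IDR peaks, which do not use the other candidates, still showed depletion at piRNA genes (35 peaks against a mean of 59.5, odds ratio 0.580). Denser candidates thus did not account for all of it. Candidates of replicate 2 were likewise denser in the clusters (2110, mean 1739) and those of replicate 1 were not (1055, mean 1109, permutation p = 0.0799). With replicate 1 alone the odds ratio at piRNA genes was still 0.492. Weak signal at piRNA starts would place summits upstream of them. Among piRNA genes, 394 had a pooled candidate summit 30 to 80 bp upstream and 361 the same distance downstream. The upstream share of these counts was 52.2% (95% exact interval 48.6 to 55.8). The bound of 55% set in advance lay inside that interval, which leaves a small excess open. Neighbouring piRNA genes can share a summit, and the interval treats the counts as independent, so it may be too narrow. The share of germ cells in these larvae was not measured, so a biological explanation was not tested.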
